A study of Homo sapiens with 6 samples.

How the data were processed

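The data were 6 RNA sequencing libraries of the human gastric cancer line NCI-N87, 3 with an EGLN3 expression plasmid and 3 with the empty plasmid, grouped by the titles and genotype given in the labels. Total RNA was taken up in Trizol and libraries followed standard Illumina protocols, per the labels. The labels give 1 day with the plasmid and 7 days of puromycin, and 5 days with the plasmid for EGLN3 replicate 3. That library was kept, and each comparison was also made without it.

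The deposited gene counts are whole numbers per gene and library, with no scaling. The submitters' processing notes name HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.20.0 and the build hg38, with no role for each. The annotation and the use of strand are not given in the sources used here. Gene identifiers and coordinates in the deposited table were compared with GENCODE release 29 on GRCh38, and 58676 of 58735 genes had a transcript there. The deposited FPKM values equal the counts divided by gene length and by 1 factor per library. From the values, that factor equals a DESeq2 size factor times the geometric mean of the library totals, so these FPKM were scaled between libraries. FPKM served as an alternative only.

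Library totals ran from 15157265 to 16767383 counts, so 1 CPM of the raw totals is about 15.2 to 16.8 counts per library. The CPM printed here also carry the TMM scaling described below, with factors from 0.9187 to 1.059. The chi-square statistic per degree of freedom between libraries of a group lay between 8.98 and 117, so no pair agreed within sampling noise. Each library was counted as 1 replicate because the labels number it so. This statistic does not tell repeat libraries of 1 culture from separate cultures.

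Counts were analysed in R 4.3.3. Genes were filtered with filterByExpr, scaled by TMM and tested with the quasi-likelihood test of edgeR 4.0.16 with robust estimation and no covariate. P-values were adjusted by Benjamini and Hochberg, and an adjusted p under 0.05 counted as a call. For a log2 fold change the SE is its size divided by the square root of the F statistic. Levels are CPM after TMM scaling. A set of 37 gene lists was fixed before the data were examined, and 35 with at least 5 tested members were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, and again with an estimated correlation and with fry. EGLN3 was left out of the lists and their background.

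Alternatives set before the data were examined were DESeq2 1.42.0, limma-voom, RLE and upper-quartile scaling, no filter, a stricter filter (1 CPM in 3 libraries), the replicate number as a block, limma on log2(FPKM + 1) and log2(FPKM + 0.1) with a minimum FPKM of 0.5 in 3 libraries or none, protein-coding genes alone, counts thinned to equal totals, and leaving out each library. After the data had been seen, further fits were added: 1 surrogate variable from svaseq (sva 3.50.0); the same with each library's trend on GC content, or on GC content and gene length, taken out as an offset; these trends without a surrogate variable; and the length slope or the side of the first axis as a term. GC content was that of the longest GENCODE transcript, held by 99.96% of the tested genes, and trends were splines with 5 degrees of freedom. The fit with the surrogate variable and both trends is the corrected fit. It has 3 residual degrees of freedom, against 4 without the surrogate variable.

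Named genes were EGLN3; the 10 protein-coding genes with the largest rise and the 10 with the largest fall among calls with a mean of at least 1 CPM and no overlap of the groups; 12 genes chosen beforehand for their place in HIF, NF-kB, proliferation or the published study; and up to 4 members with the smallest adjusted p of each list that passed camera or had 3 or more calls. Applied to the corrected fit, the same rule was chosen after seeing the data, left out genes of the Y chromosome, and judged overlap on corrected values. VEGFA, NFKBIA, BIRC3, RELB, DTX3L, STUB1, CYP51A1, PMVK, SRXN1, LDHB, STAG3L1 and NMRAL2P were named outside the rule after their values were seen.

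The procedures were tested on simulated data: 200 of the real genes were changed by 1.25, 1.5 or 2-fold in counts drawn from the means and spread of the surrogate variable fit. With the first axis in the simulated libraries, edgeR alone recovered 0% at each size, and the corrected fit recovered 41.8%, 82.1% and 87.9%, with 11 false calls among 152. Without the axis, edgeR alone recovered 38.8%, 76.1% and 84.8%. These recovery shares come from 1 draw with the axis and 1 without. The draws carry the same axis term and spread that the surrogate variable fit assumes, so they may overstate recovery in the real libraries. In 5 draws with the axis and no changed gene, the corrected fit made 0 to 1 calls. The surrogate variable fit without GC and length correction also made 0 to 1, against 741 calls in the data. The draws left out the group difference of the data, its GC trend included, so they cannot show how either fit handles that trend. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Statements in the report describe measurements and tests, and interpretation is kept to the closing section.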

Results

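RNA was sequenced from NCI-N87 cells, an established human gastric cancer line with many copies of ERBB2, after the cells had received a lentiviral expression plasmid. In 3 libraries the plasmid carried EGLN3, and in 3 control libraries it was empty. EGLN3, also called PHD3, is a prolyl hydroxylase best known for marking the hypoxia-inducible factors (HIF) for degradation when oxygen is present. Cells were under puromycin for 7 days after 1 day with the plasmid, except that the label of EGLN3 replicate 3 gives 5 days. The comparison asked what EGLN3 at a raised level does to the transcriptome of these cells. Total gene counts were 16767383, 15948514 and 16498479 in control replicates 1 to 3, and 16531328, 16077210 and 15157265 in EGLN3 replicates 1 to 3. Of 58735 annotated genes, 15726 had enough counts to be tested. The labels do not say that replicates came from separate cultures, so p-values measure at most the spread between these libraries, which may be technical.

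EGLN3 itself rose from near absence to a high level in each of the 3 libraries that carried it. The gene (ENSG00000129521) lies on the minus strand of chromosome 14, from 33924231 to 34462774 in GRCh38, and its annotated span overlaps that of SPTSSA. Its level was 0.616 ± 0.0749 CPM (counts scaled to library size) in controls (SD, n = 3) and 1280 ± 692 CPM with the EGLN3 plasmid (SD, n = 3), 2080 times the control mean. The log2 fold change was 11 (SE 0.72; edgeR quasi-likelihood test, adjusted p = 0.031). Control libraries held 10, 11 and 9 EGLN3 counts, and EGLN3 replicates 1 to 3 held 7298, 27674 and 27494. The lowest EGLN3 library stood 685 times above the highest control. EGLN3 replicates differed among themselves, since the mean of replicates 2 and 3 was 3.49 times the level of replicate 1. These counts do not separate plasmid transcripts from those of the native gene. The adjusted p passed 0.05 in 1 of the 6 fits that left out 1 library, the one without EGLN3 replicate 1. Without control replicates 1, 2 and 3 it was 0.4, 0.67 and 0.56, and without EGLN3 replicates 2 and 3 it was 0.15 and 0.065, with a log2 fold change between 10.73 and 11.41 over the 6 fits.

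**Figure D1:**
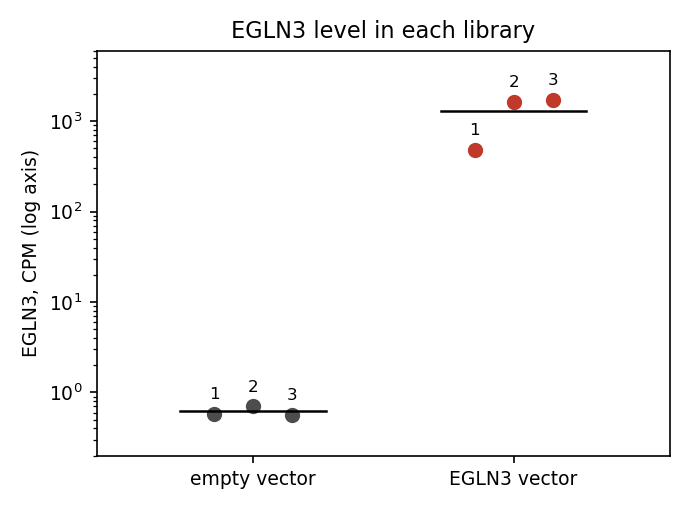
EGLN3 level in each library, in CPM on a log axis; points are libraries with their replicate number, and lines are group means. The 3 control libraries lie between 0.5649 and 0.7023 CPM, and the EGLN3 libraries at 481.4, 1640 and 1717 CPM.

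In the comparison as designed before the data were examined, EGLN3 was the one gene that passed. JMJD8, a protein with a Jumonji domain, was lower in all 3 EGLN3 libraries without passing over all genes. Interferon-stimulated genes were higher as a group, and genes of glycolysis and of S phase were lower, each by a small amount. None of these group calls held with an estimated correlation between genes (camera, adjusted p = 0.12, 0.72 and 0.38). Neither the NF-kB targets nor the HIF targets passed as a group.

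Of 15726 genes, 1 had an adjusted p under 0.05 in edgeR's quasi-likelihood test, and 174 had an unadjusted p under 0.05. DESeq2 called 1 gene with 163 at an unadjusted p under 0.05, and limma-voom called 0 with 181. Each of these unadjusted counts is below what chance alone would give on average, so they do not point to further changed genes. The corrected fit described below had 2062 genes at that mark, with p-values that may be too small. JMJD8 (ENSG00000161999) lies on the minus strand of chromosome 16, from 681671 to 684528, and shares 1200 bp with STUB1 on the opposite strand. It measured 28.2 ± 3.52 CPM in controls and 17.8 ± 0.581 CPM with EGLN3 (SD, n = 3 each). Its log2 fold change was -0.66 (SE 0.14; edgeR unadjusted p = 0.0026, adjusted p = 1 over all genes). STUB1 had a log2 fold change of -0.28 (SE 0.25). Because strand use in counting is not given in the sources used here, reads from the shared part could belong to either gene. Among 12 genes fixed in advance, JMJD8 was the 1 that passed when adjusted over the list alone (edgeR, adjusted p = 0.031). It was put on that list because the published study names it beside EGLN3, so this count is not independent evidence.

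The other 11 fixed genes did not pass in the uncorrected fit. HIF1A and EPAS1, the oxygen-regulated HIF subunits, had log2 fold changes of 0.19 (SE 0.22) and 0.05 (SE 0.20). EGLN1 and EGLN2, the other HIF prolyl hydroxylases, were at 0.09 (SE 0.15) and -0.15 (SE 0.28), and VHL, which recognises hydroxylated HIF, was at -0.15 (SE 0.19). RELA, the NF-kB subunit p65, had a log2 fold change of 0.00 (SE 0.14). ERBB2, at 10000 ± 630 CPM in controls and 9090 ± 558 CPM with EGLN3, had one of -0.14 (SE 0.15). The proliferation marker MKI67 was at -0.06 (SE 0.33), the cell cycle inhibitor CDKN1A at -0.03 (SE 0.19), CCND1 at -0.01 (SE 0.17) and MYC at 0.00 (SE 0.12). Each had an edgeR adjusted p of 1 over all genes.

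Of 35 gene lists fixed in advance and tested with camera at a preset correlation, 5 passed. Interferon-stimulated genes had a median log2 fold change of 0.17, with 35 of 38 higher, 0 called one by one, and 0 called when adjusted over the list alone (camera, adjusted p = 3.8e-06, and adjusted p = 0.12 with an estimated correlation). The list's median deviation from the mean of all libraries was -0.07, -0.09 and -0.10 in controls, against 0.05, 0.13 and 0.18 with EGLN3. IFIT5, an antiviral RNA-binding protein, had a log2 fold change of 0.40 (SE 0.15), and IFIT2 one of 0.33 (SE 0.13). Replication-dependent histones had a median of 0.30, with 8 of 8 higher (camera, adjusted p = 9.5e-05, and adjusted p = 0.56 with an estimated correlation). The histone list's median per library overlapped between groups, at -0.34, -0.15 and 0.00 in controls and 0.42, 0.15 and -0.10 with EGLN3. HIST1H4H was at 0.64 (SE 0.17) and HIST2H2BE at 0.46 (SE 0.15). Glycolysis genes had a median of -0.15, with 19 of 20 lower (camera, adjusted p = 9.5e-05, and adjusted p = 0.72 with an estimated correlation). Its medians per library overlapped too, at -0.04, 0.15 and 0.14 against 0.10, -0.12 and -0.24. PFKP, a phosphofructokinase, was at -0.33 (SE 0.13), and the lactate exporter SLC16A3 at -0.32 (SE 0.16). S phase genes had a median of -0.08, with 27 of 37 lower (camera, adjusted p = 0.015, and adjusted p = 0.38 with an estimated correlation). The replication helicase subunits MCM7 and MCM3 were at -0.29 (SE 0.18) and -0.19 (SE 0.12). Ribosomal protein genes had a median of -0.09, with 38 of 42 lower (camera, adjusted p = 0.033, and adjusted p = 0.96 with an estimated correlation). That median turned to 0.131, 0.04 and 0.054 without EGLN3 replicate 3, EGLN3 replicate 2 and control replicate 3. Without control replicates 1 and 2 and EGLN3 replicate 1 it was -0.267, -0.022 and -0.553. When adjusted over each list alone, 0 members of these 5 lists were called, while 2 interferon-stimulated, 2 glycolysis and 2 histone genes had an edgeR unadjusted p under 0.05. No list passed with an estimated correlation.

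The libraries differed along an axis that the plasmid does not define. The first principal component held 70% of the variance and placed control replicates 1 to 3 at -36.2, 11.5 and 34.4, and EGLN3 replicates 1 to 3 at 59.4, -23.3 and -45.9. Ribosomal protein genes followed it, with 42 of 42 higher toward EGLN3 replicate 1 and control replicate 3, as did 31 of 33 genes of oxidative phosphorylation and 11 of 13 mitochondrial transcripts. Short genes and genes of high GC content were higher on the same side (across genes, Spearman's rho of the loading was -0.448 with gene length and 0.358 with GC content; genes are not independent replicates). The second component, with 11% of the variance, placed controls at -11.3, -20.8 and -11.1 and EGLN3 libraries at 19.2, 7.81 and 16.2. Its loading also followed GC content (rho -0.431 across genes). In 1 draw of simulated counts that carried the first axis, edgeR without a term for it recovered 0% of genes changed 2-fold.

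**Figure D2:**
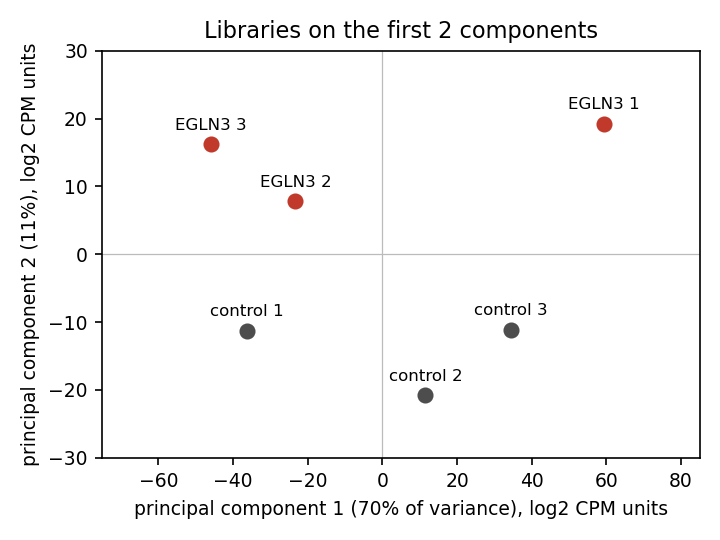
Libraries on the first 2 principal components of log2 CPM, in log2 CPM units; points are libraries, grey for control and red for EGLN3. The first component (70% of variance) mixes the groups, and on the second (11%) controls lie at or below -11.1 and EGLN3 libraries at or above 7.81.

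**Figure D3:**
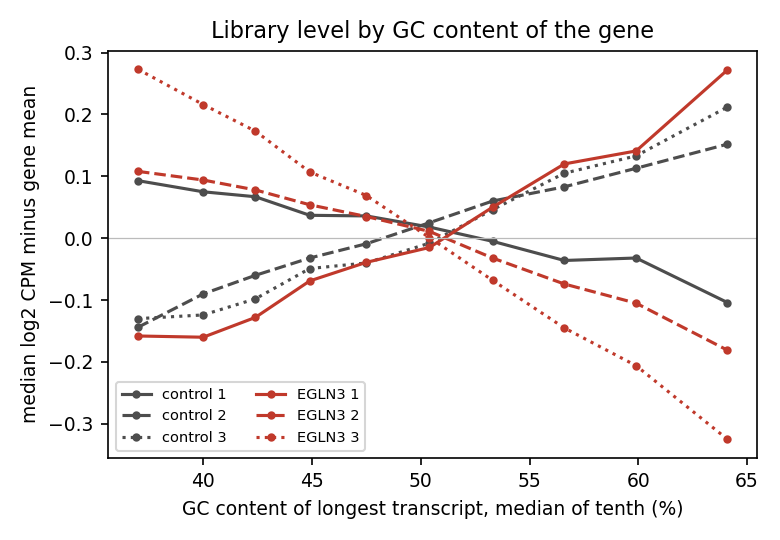
Median deviation of log2 CPM from each gene's mean over the 6 libraries, for 10 equal bins of the tested genes ordered by GC content of their longest transcript (x axis, %, each point at its bin's median). Lines are libraries, grey for control and red for EGLN3; in the bin of highest GC content they run from -0.325 in EGLN3 replicate 3 to 0.272 in EGLN3 replicate 1.

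A fit chosen after seeing the data took this axis and the GC trend out before comparing the groups. It added 1 surrogate variable to the model and removed each library's smooth trends on GC content and gene length, and is called the corrected fit. The surrogate variable and trends were estimated from the same libraries and then treated as known. The common dispersion, edgeR's measure of spread between libraries, fell from 0.0589 in the uncorrected fit to 0.00223. The SEs and p-values of the corrected fit leave out the uncertainty of that estimation and may be too small. In it 152 genes changed with EGLN3, 49 upward, EGLN3 included, and 103 downward. Interferon-stimulated, cholesterol synthesis and NRF2 target genes were among those that rose, and ribosomal protein, respiratory chain and glycolysis genes among those that fell. Apart from EGLN3 the changes were small, with a median size of 0.27 on the log2 scale over the 151 other genes, and quartiles of 0.22 and 0.35.

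Of the 151, 41 had groups that did not overlap in plain CPM and 110 overlapped before the correction, while 984 of all 15726 tested genes did not overlap. The count was 109 with limma-voom, 108 of them among the 152, and 123 with DESeq2, 104 of them among the 152, under the same correction. DESeq2 gave no adjusted p for 11281 of the 15726 genes. It was 36, 58 and 50 without EGLN3 replicates 1, 2 and 3, and 741 with the surrogate variable but no GC and length correction, so the number of genes depends on both choices. The corrected fit put 11 lists past the threshold, with 6 and 7 without EGLN3 replicates 1 and 2, and 5 without the filter on low counts. With an estimated correlation no list passed in the corrected fit (camera, smallest adjusted p = 0.18, for interferon-stimulated genes). Of the 152 genes, 120 were also called without the GC and length correction.

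Some interferon-stimulated genes rose with EGLN3 in the corrected fit. Of 38 measured, 6 rose and 0 fell, 37 had a positive log2 fold change, and 16 were called when adjusted over the list alone (median log2 fold change 0.14; camera, adjusted p = 1e-11, and adjusted p = 0.18 with an estimated correlation). ISG15, a ubiquitin-like modifier, rose by 23.7% (log2 fold change 0.31, SE 0.04; edgeR, adjusted p = 0.00043). OAS2, a sensor of double-stranded RNA, rose by 24.4% (0.31, SE 0.05), and IFI44L by 25.8% (0.33, SE 0.05). SAMD9, IFIT5 and DTX3L, a ubiquitin ligase that pairs with PARP9, were the other members that rose, with log2 fold changes of 0.22, 0.29 and 0.20. In plain CPM, ISG15 ran from 521.3 to 903 in controls and from 547.7 to 1398 with EGLN3, so its groups overlapped before the correction.

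Enzymes of sterol synthesis and targets of NRF2 included several genes that rose. Of 25 cholesterol synthesis genes, 4 rose and 0 fell, and when adjusted over the list alone 7 were called higher and 2 lower (median 0.03; camera, adjusted p = 0.042, and adjusted p = 0.53 with an estimated correlation). The list did not pass in the uncorrected fit or with the surrogate variable alone (camera, adjusted p = 0.45 and 0.39). MSMO1, a sterol methyl oxidase, rose by 30% (log2 fold change 0.38, SE 0.05; edgeR, adjusted p = 0.00035), and INSIG1, which holds the sterol sensor SCAP in the endoplasmic reticulum, rose by 27.5%. HMGCS1 and the squalene epoxidase SQLE rose by 18.6% and 16.1%. The members called lower were CYP51A1 at -0.47 (SE 0.14) and PMVK at -0.25 (SE 0.08), and 9 of the 25 were lower. Of 23 NRF2 targets, 3 rose and 0 fell, and when adjusted over the list alone 9 were called higher and 1 lower, SRXN1 at -0.52 (SE 0.19) (median 0.03; camera, adjusted p = 0.022, and adjusted p = 0.4 with an estimated correlation). HMOX1, which breaks down heme, rose by 50.6% (log2 fold change 0.59, SE 0.09; edgeR, adjusted p = 7e-04). The ferritin light chain FTL rose by 25.1% and the malic enzyme ME1 by 16.3%. Each of these list calls was lost in 4 of the 6 corrected fits that left out 1 library.

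Components of the ribosome and the respiratory chain were lower by small amounts in the corrected fit, but their direction depends on how the first axis is modelled. With the side of that axis as a term instead, both lists passed in the other direction, with medians of 0.126 for ribosomal proteins and 0.139 for oxidative phosphorylation (camera, adjusted p = 0.007 and 0.0078). In the uncorrected fit oxidative phosphorylation had a median of -0.01 (camera, adjusted p = 0.44). Its median there was -0.158, 0.013 and 0.08 without control replicates 1, 2 and 3. Without EGLN3 replicates 1, 2 and 3 it was -0.333, 0.07 and 0.125. Of 42 ribosomal protein genes, 9 fell and 0 rose, and 20 were called when adjusted over the list alone (median -0.11; camera, adjusted p = 2.9e-07, and adjusted p = 0.62 with an estimated correlation). RPS3 fell by 21% (log2 fold change -0.34, SE 0.05; edgeR, adjusted p = 7e-04), RPS23 fell by 17.5%, RPL24 fell by 15% and RPL5 fell by 14.8%. With the surrogate variable but no GC and length correction, RPS3 and RPS23 were still called. RPL24, at -0.14, and RPL5, at -0.1, were not (edgeR, adjusted p = 0.11 and 0.23). In plain CPM the highest RPS3 level of the 6 libraries was 2394, in EGLN3 replicate 1, so its groups overlapped before the correction. These genes have many processed pseudogenes, so the division of their reads is uncertain, and the list followed the first axis in 42 of 42 members. Of 33 genes of oxidative phosphorylation, 3 fell and 0 rose, and 9 were called when adjusted over the list alone (median -0.06; camera, adjusted p = 0.002, and adjusted p = 0.53 with an estimated correlation). NDUFV1 of complex I fell by 13.8%, UQCRB of the cytochrome bc1 complex fell by 13.8%, and the ATP synthase subunit ATP5F1A fell by 13.5%. With the surrogate variable but no GC and length correction, NDUFV1 was still called, at -0.3 (edgeR, adjusted p = 0.0015). UQCRB, at -0.07, and ATP5F1A, at -0.16, were not (edgeR, adjusted p = 0.47 and 0.087). This list followed the first axis too, in 31 of 33 members.

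Glycolysis and cell cycle genes fell in small numbers. Of 20 glycolysis genes, 2 fell and 0 rose, and when adjusted over the list alone 10 were called lower and 1 higher, LDHB at 0.21 (SE 0.07) (median -0.11; camera, adjusted p = 0.00019, and adjusted p = 0.53 with an estimated correlation). PFKP fell by 15% (log2 fold change -0.23, SE 0.05; edgeR, adjusted p = 0.017) and SLC16A3 fell by 11.8% (edgeR, adjusted p = 0.0496). The list followed the first axis in 17 of 20 members. Of 37 S phase genes, 1 fell, MCM7 by a log2 fold change of -0.20 (SE 0.05), with 9 called when adjusted over the list alone (median -0.09; camera, adjusted p = 3.1e-05, and adjusted p = 0.53 with an estimated correlation). Of 35 genes of G2 and mitosis, 1 fell, the topoisomerase TOP2A by a log2 fold change of -0.19 (SE 0.05), with 5 called when adjusted over the list alone (median -0.08; camera, adjusted p = 0.0075, and adjusted p = 0.4 with an estimated correlation). This list did not pass in the uncorrected fit, with a median of -0.02 and 15 higher (camera, adjusted p = 0.83). Nor did it with the surrogate variable alone (camera, adjusted p = 0.48). TOP2A was then at -0.13 (edgeR, adjusted p = 0.14), and its groups overlapped in plain CPM. MKI67 did not pass (log2 fold change -0.11, SE 0.05; edgeR, adjusted p = 0.3). Of 8 replication-dependent histone genes, 3 rose and 5 were called when adjusted over the list alone (median 0.31; camera, adjusted p = 3.1e-05, and adjusted p = 0.29 with an estimated correlation). HIST1H2BK rose by 35.4%, HIST2H2BE by 37.8% and HIST1H1C by 26.7%. Of the 8, 7 followed the first axis. Reads of these histones may be shared with near-identical family members.

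Immediate early genes and genes of fatty acid oxidation passed as lists with 0 members called one by one. The first had a median of 0.10, with 12 of 17 higher and 2 called when adjusted over the list alone (camera, adjusted p = 0.012, and adjusted p = 0.4 with an estimated correlation). DUSP1, a phosphatase of MAP kinases, had a log2 fold change of 0.31 (SE 0.09; edgeR, adjusted p = 0.12). Fatty acid oxidation had a median of -0.07, with 20 of 24 lower and 0 called when adjusted over the list alone (camera, adjusted p = 0.013, and adjusted p = 0.61 with an estimated correlation). The calls of these lists were each lost in 3 of the 6 corrected fits that left out 1 library. Neither list passed in the uncorrected fit (camera, adjusted p = 0.44 and 0.45) or with the surrogate variable alone (camera, adjusted p = 0.42 and 0.21). DECR1, an enzyme that handles unsaturated fatty acids, was at -0.18 (SE 0.06; edgeR, adjusted p = 0.15). Of the 12 fixed genes, JMJD8 passed over all genes in the corrected fit and fell by 29.4% (log2 fold change -0.50, SE 0.08; edgeR, adjusted p = 0.0018). STUB1, which overlaps it, was at -0.12 (SE 0.08; edgeR, adjusted p = 0.57). VHL was the other fixed gene that passed when adjusted over the list alone (log2 fold change -0.18, SE 0.06; edgeR, adjusted p = 0.038), with an adjusted p of 0.17 over all genes.

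**Figure D4:**
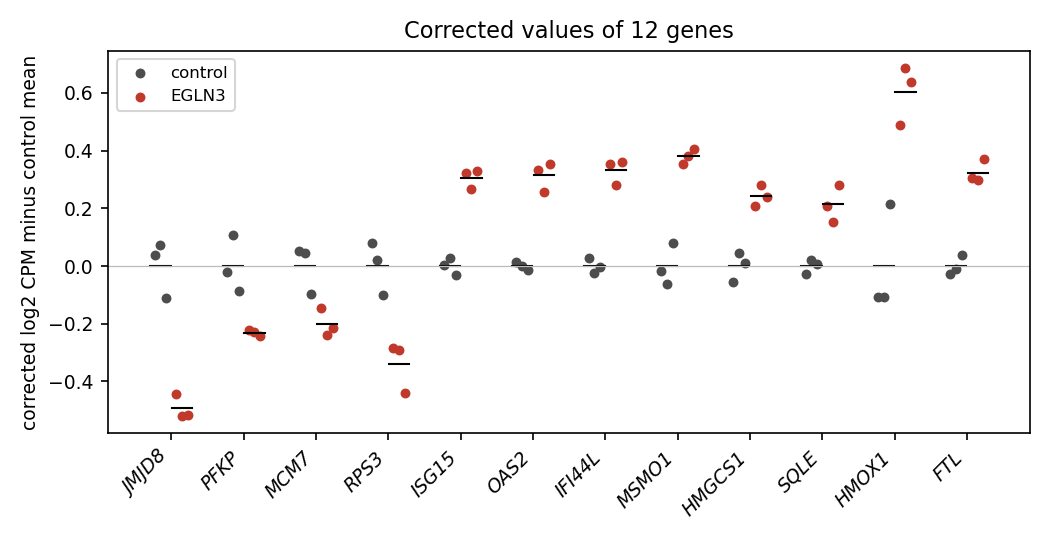
Corrected log2 CPM minus the control mean for 12 named genes; points are libraries, grey for control and red for EGLN3, and lines are group means. The correction was fitted with the groups in the model, so the points show the fitted separation rather than raw levels; HMOX1 lies highest (log2 fold change 0.59) and JMJD8 lowest (-0.50).

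HIF targets and NF-kB targets did not pass as lists in either fit. Of 30 HIF targets, 1 fell in the corrected fit, SLC16A3, and VEGFA, a secreted angiogenic factor, was at 0.11 (SE 0.07; edgeR, adjusted p = 0.54). The list's median was -0.06 (camera, adjusted p = 0.23). Of 22 NF-kB targets, 2 rose, BIRC3 and RELB, with log2 fold changes of 0.36 (SE 0.07; edgeR, adjusted p = 0.0041) and 0.37 (SE 0.09; edgeR, adjusted p = 0.04). BIRC3 is a ubiquitin ligase of the inhibitor of apoptosis family, and RELB is a subunit of the non-canonical NF-kB pathway. The inhibitor NFKBIA was at 0.00 (SE 0.11), and the median of the list was 0.03 (camera, adjusted p = 0.18). RELA was at 0.09 (SE 0.05; edgeR, adjusted p = 0.48).

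**Figure D5:**
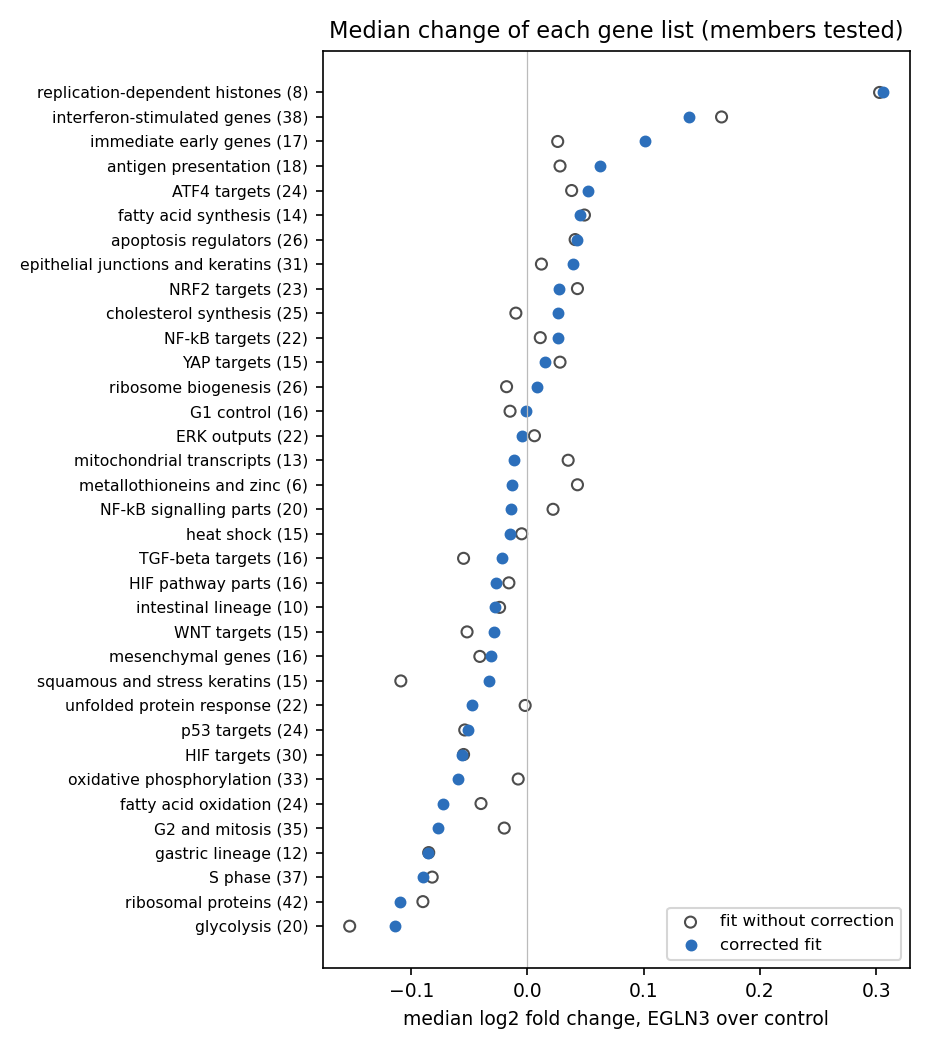
Median log2 fold change of each of the 35 gene lists, EGLN3 over control, with the number of members tested in brackets; open circles are the uncorrected fit and blue points the corrected fit. Histones (0.306) and interferon-stimulated genes (0.139) lie highest in the corrected fit, and glycolysis (-0.114) and ribosomal proteins (-0.11) lowest.

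Among genes that met the naming rule, those with the largest changes in the corrected fit had varied functions. The rule took protein-coding genes whose groups did not overlap in corrected values. STAG3L1 and NMRAL2P, which did not meet it, rose by 0.973 (SE 0.131) and 0.685 (SE 0.114) on the log2 scale. MUC13, a membrane mucin, rose by 49.6% (log2 fold change 0.58, SE 0.10; edgeR, adjusted p = 0.004), and GAST, which encodes the hormone gastrin, rose by 40% (0.48, SE 0.08). The small heat shock protein HSPB8 rose by 37.4%, the phosphatidate phosphatase LPIN1 by 35.7%, and the extracellular chaperone CLU by 33.4%. FOXL1, a forkhead transcription factor, fell by 31.7% (-0.55, SE 0.13; edgeR, adjusted p = 0.028), and the receptor ROR1 fell by 28.7%. The matrix protein TNC fell by 26.7%, and PLAT, tissue plasminogen activator, fell by 23.9%. The adenylate cyclase ADCY7 fell by 25.2%, NDUFB1 of complex I by a log2 fold change of -0.41 (SE 0.09), and the mitochondrial ribosomal protein MRPL52 by one of -0.39 (SE 0.09). With the surrogate variable but no GC and length correction, NDUFB1 was at -0.29 and not called (edgeR, adjusted p = 0.057). The splicing factor SRSF9 fell by 30.9%, and PSMC3IP, a factor of meiotic recombination, fell by 26.7%. NPIPA7 rose by 116%, but it belongs to a family of near-identical copies, and its level was 1.47 ± 0.731 CPM in controls. In plain CPM the groups overlapped for GAST, LPIN1, CLU, ROR1, TNC, PSMC3IP, ADCY7, NDUFB1, MRPL52 and HMOX1. ADCY7 had a log2 fold change of -0.31 in the uncorrected fit (edgeR unadjusted p = 0.65), which turned positive without control replicate 1 and without EGLN3 replicate 1. JMJD8, ADCY7, SRSF9, PSMC3IP, SLC16A3, MCM7, HMGCS1, ATP5F1A, RPS23, RPL5, DECR1, IFIT2, ERBB2, RELA, CCND1 and DTX3L each overlap another tested gene, which leaves the division of their reads uncertain.

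Markers of other cell types were low or did not move. Of 16 fibroblast and endothelial markers, 3 had enough counts to be tested, COL1A1 at 4.46 CPM, TAGLN at 55.4 CPM and VWF at 0.771 CPM, with 0 called in either fit. Of 14 immune markers, CD14, CD79A and CORO1A were tested, at 2.47, 1.34 and 12.3 CPM, also with 0 called. For these 6 genes the smallest edgeR adjusted p of the corrected fit was 0.64.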

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

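The fits with a surrogate variable, a GC or length correction, a length slope or the side of the first axis, and all alternatives of the corrected fit, were chosen after the results were seen, and all other alternatives before the data were examined. EGLN3 was higher under each alternative run, but its call was lost with limma-voom (log2 fold change 10.75, adjusted p = 0.23), with the replicate block (10.83, adjusted p = 0.26) and with log2(FPKM + 1) with and without a filter (7.12 in both, adjusted p = 0.067 and 0.22). The count of called genes was then 0 in each of these 4 fits. Leaving out 1 library gave 0 to 1 genes and an EGLN3 log2 fold change of 10.73 to 11.41. The count of called genes was 741 with the surrogate variable, 126 with GC correction added, 152 with GC and length correction, and 792 with the length slope. The count of lists, 5 as designed, was 11 with the surrogate variable and GC correction, 11 with length added, 8 with GC and length correction alone, 0 with an estimated correlation and 1 with fry (interferon-stimulated genes), and 3 to 7 without 1 library. Ribosomal protein genes reversed to a median of 0.126 with the side of the first axis as a term, and oxidative phosphorylation to 0.139. Without 1 library the ribosomal median ran from -0.553 to 0.131, and the cause was not tested. The 11 lists of the corrected fit became 6 without GC and length correction, 5 without the filter, and 6, 7 and 10 without EGLN3 replicates 1, 2 and 3. No list of the corrected fit passed with an estimated correlation. With fry, interferon-stimulated genes, replication-dependent histones and immediate early genes passed in that fit (fry, adjusted p = 0.021, 0.021 and 0.025). The other lists past the camera threshold did not, with values from 0.13 (G2 and mitosis) to 0.23 (fatty acid oxidation). In the corrected fit, the 152 calls became 741 without GC and length correction, 1 without the surrogate variable, 431 without the filter, which tested 32719 genes, and 36 to 187 without 1 library (36, 58 and 50 without EGLN3 replicates 1, 2 and 3). With the replicate block they became 694. The replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at -0.79, -0.18 and -0.67, and 0 of 6 libraries correlated best with its own number. Other changes lay among named genes and single lists: 177 gene values gained a call against the uncorrected fit, and 222 lost one against the corrected fit. Depth differed little between libraries, and thinning to equal totals gave 1 gene, and 181 in the corrected fit.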

Other observations

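The tests of the EGLN3 call (library depth, EGLN3 replicate 3, splits) were set before the data were examined, and those of library depth on the first axis and of 1 library for the corrected calls and the interferon-stimulated genes after these patterns but before the test values were seen. Tests chosen only after the result was seen are those of the EGLN3 level, GC content and gene length on the first axis, the splits of the lists and of the corrected fit, the simulation, the GC and length tests of the surrogate variable calls and of the interferon-stimulated genes, and all list values of the corrected fit.

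Several further genes changed in the corrected fit, some of them members of lists that did not pass, and they are named here after their values were seen. Among those that fell, FN1, fibronectin, had a log2 fold change of -0.24 (SE 0.06), the growth factor TGFB2 -0.26 (SE 0.06), the integrin subunit ITGB5 -0.30 (SE 0.05), and the hyaluronan-binding protein CEMIP -0.22 (SE 0.04). GDF15, a stress-induced cytokine, was at -0.23 (SE 0.05), and KRT13, a keratin of squamous epithelia, at -0.34 (SE 0.07). SLPI, a secreted protease inhibitor, rose by 0.32 (SE 0.05) on the log2 scale, SCD, the stearoyl-CoA desaturase, by 0.25 (SE 0.04), and APOL1 by 0.39 (SE 0.07). Of genes of the replication and cell cycle machinery, CDK4 was at -0.24 (SE 0.05), the polymerase subunit POLD1 at -0.27 (SE 0.05), CKS2 at -0.24 (SE 0.06) and the condensin subunit NCAPD2 at -0.21 (SE 0.05). Each of these had an edgeR adjusted p under 0.05 in that fit, and CEMIP, CDK4 and NCAPD2 overlap another tested gene.

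Among the 35 lists, 5 had medians per library that did not overlap between the groups before any correction, 14.3% where chance gives 10%. TGF-beta targets stood at 0.09, 0.07 and 0.07 in controls and -0.08, -0.08 and -0.07 with EGLN3, but the list did not pass (camera, adjusted p = 0.13; 0.38 in the corrected fit). S phase genes stood at 0.04, 0.12 and 0.05 against -0.08, -0.01 and 0. Genes of the gastric lineage stood at 0.09, 0.11 and 0.06 against -0.19, -0.01 and 0, with 0 called in either fit, 0 with an edgeR unadjusted p under 0.05 in the uncorrected fit, and a camera adjusted p of 0.063.

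In the uncorrected fit 2 of the 10 splits of the 6 libraries, the real one included, gave at least 1 gene, and the split of control replicate 1 with EGLN3 replicates 2 and 3 against the rest gave 7105, which points to a structure of the libraries, and 10 splits are too few for a share under 0.05. For that 1 gene, EGLN3, 100% kept direction and an unadjusted p under 0.05 without EGLN3 replicate 3, though its edgeR adjusted p was then 0.065. After thinning for library depth 100% passed. Its lowest EGLN3 library stood 685 times above the highest control, so the test at an unadjusted p could hardly have failed. The thinning test could have, since the edgeR adjusted p was 0.031 before it. Library totals differed little, however, so thinning changed little. No conclusion is drawn from either test.

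The first pattern is the axis that held 70% of the variance and did not follow the groups. Library depth is argued against, since thinning to equal totals left it at 70.1%. The EGLN3 level as the whole cause is argued against too, since control libraries, whose plasmid lacks EGLN3, spanned 67.1% of the axis's whole range. A part tied to that level is not excluded. The EGLN3 libraries with 481.4, 1640 and 1717 CPM of EGLN3 lay at 59.4, -23.3 and -45.9 on the axis. GC content and gene length as the whole cause are argued against, since after both trends were removed the first axis held 65.8% of the remaining variance, and the variance along the axis as first computed was 60.4% of that before (77.8% for the axis computed anew), so both trends may account for a part of it. Its relation to short genes, ribosomal proteins and mitochondrial transcripts is consistent with differences in RNA integrity or library preparation, which were not tested, and a difference between cultures stays open as well.

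The second pattern is the set of genes called once the axis was modelled. A trend on GC content is a candidate explanation for part of the 741 calls of the surrogate variable fit. The median GC content of the lower calls exceeded that of the higher calls by 19.8 percentage points. When the trends were removed, the median size of the log2 fold change fell by 34.4%, with 120 of the genes still called. These genes were chosen for large estimates in the same libraries, so part of that size would stay under a GC cause too. The fall therefore does not decide whether the trends are the whole cause. For the 621 genes whose call ended, the median size went from 0.253 to 0.155 while the median SE went from 0.061 to 0.056, so the calls ended because the estimates shrank. For the 152 corrected calls, 98.7% or more kept their direction with an unadjusted p under 0.05 without any single library. This does not argue against 1 library as the cause. The genes were chosen at an adjusted p under 0.05 on data that include the libraries left in, so most would pass the looser mark. Without EGLN3 replicates 1, 2 and 3, only 36, 58 and 50 genes were called. Of these, 29, 53 and 46 were among the 152. False calls from fitting the axis stay open: simulated draws gave at most 1 call, but simulated counts need not hold all structure of the libraries, and 1 of the 10 splits of the 6 libraries (the real one, with 152) gave as many, where that same other split gave the highest other count, 32, with 10 lists past the threshold, the highest other count, against 11 for the real one (1 of the 10 splits gave as many lists), and 10 splits are too few for a share under 0.05.

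The third pattern is the higher level of interferon-stimulated genes with EGLN3. The corrected median was 82.9% of the uncorrected one. For the first axis this decides nothing, because the surrogate variable was fitted with the groups in the model and could hardly take out a group difference. Adding the GC and length trends to the surrogate variable took the list's median from 0.132 to 0.139, so these trends are argued against as its whole cause. A part played by them stays open, since the same step cut the members called from 14 to 6. Members moved both ways, with IFI44L going from 0.41 to 0.33 and ISG15 from 0.2 to 0.31. That 1 library is the cause is argued against, since the lowest corrected median without any single library was 0.116. Chance is not settled. Of the 10 splits, 3, the real one included, gave at least as many lists past the threshold as the real one (5, with 5 as the highest other). That count covers all 35 lists and does not show how this list fares in other splits, and 10 splits are too few for a share under 0.05. The list's adjusted p was 0.12 (camera with an estimated correlation) and 0.0029 (fry), and in the corrected fit 0.18 and 0.021 by the same tests. Whether the EGLN3 protein or a difference between preparations lies behind it was not tested.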
